A study of Homo sapiens with 4 samples.

How the data were processed

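Small RNA libraries of HFE-145 cells, an immortalised human gastric epithelial line, were made from total RNA isolated with easy-BLUE, using an NEB multiplex small RNA kit, per the labels' protocols. The 4 samples were 2 carrying the vector and 2 overexpressing YAP5SA, and each sample's group and replicate number came from its title. The labels call the samples duplicates and do not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

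The authors deposited 1 table with a line per mature miRNA. Its raw read counts were whole numbers per miRNA with no normalization, per the file headers. Its log2 values were log2 of a normalized read count, per the file headers; the highest value was 15.8 in each library and 19.5% of the sorted values were equal in the 4 libraries within 0.01, and the method is not given in the sources used here. The fold change in the authors' deposited table equalled the ratio of the group means of the linear normalized counts, YAP5SA over vector. The p-value column of the authors' deposited table came from a test that is not given in the sources used here. The submitters' processing notes name FastQC and the hg19 build. The aligner, the counting tool, its use of strand and the miRNA annotation version are not given in the sources used here. The table held 2039 miRNAs, and 3 lines with no miRNA name or value were left out.

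The deposited counts were tested with edgeR 4.0.16 in R 4.3.3, using its quasi-likelihood test with TMM scaling, its default filter on low counts, and group as the model's term. Adjustment was by Benjamini-Hochberg over all miRNAs tested, with a threshold of 0.05 and no fold minimum. The filter kept 602 miRNAs holding 96.9% of all counts and left out 1437. The SE of a log2 fold change was approximated as its size divided by the square root of the test's F statistic. CPM values are TMM-normalized counts scaled to library size (CPM), given as mean ± SD over 2 samples. The common dispersion was 0.106.

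Lists of related miRNAs were tested with limma 3.58.1 by camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for lists with at least 3 tested members, with Benjamini-Hochberg adjustment over those lists. Camera with an estimated correlation and fry were run beside it. The 25 lists were the miR-17~92 cluster and paralogs, the let-7, miR-200, miR-29, miR-34/449, miR-15/16, miR-30, miR-26, miR-130/301 and miR-181 families, the miR-23/27/24, miR-221/222, miR-183/96/182 and miR-143/145 clusters, the miR-10/99/100/125 and miR-192/194/215 groups, gastric epithelial miRNAs, the DLK1-DIO3 and C19MC clusters, and miRNAs of embryonic stem, blood, muscle, neural, endothelial and liver cells. The lists, the tests, the first set of alternatives and the rule for naming miRNAs were fixed before the data were examined. That rule took the 12 higher and 12 lower miRNAs with the largest log2 fold change past the threshold, with a mean of at least 20 CPM and groups that did not overlap. It added the 8 most abundant miRNAs, up to 4 abundant members of each list that passed, and any list member past the threshold.

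The steps were tested on simulated data for the comparison of YAP5SA with vector, with 20 simulations of 602 miRNAs and 200 planted changes. The test recovered 18.2% of 2-fold, 78.6% of 4-fold and 98.3% of 8-fold changes, and 3.52% of its calls were false. In the list test, a miR-200 family lowered 2-fold passed in 10.0% of simulations and a family lowered 4-fold passed in 100.0%, with the 2 folds planted in alternate simulations. Simulated counts were drawn independently for each miRNA, with no correlation within lists and no shift of rare miRNAs. These rates may therefore not hold for the real libraries.

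Ratios of miRNAs with 1 to 3 counts over both vector libraries carry an exact binomial 95% interval of pooled counts, scaled by effective library size. For a miRNA with 0 counts in the vector group, the ratio was set against 3 counts over the group, without error in the YAP5SA counts. The intervals cover counting error only, because reads were counted without molecular identifiers. Positions are on GRCh38 from GENCODE 29, by matching the table's mature sequences to annotated miRNA transcripts, since no hg19 annotation was used here. Alternatives were other scalings, other filters, a replicate block, each sample left out, DESeq2 1.42.0, limma-voom and a fold minimum. Added after the data were examined were a filter at a mean of 100 CPM, scalings from abundant or from rarely counted miRNAs, and limma on the authors' log2 values. Random lists for the closing tests drew each member from its 20 nearest neighbours in mean CPM. Sequence searches and random lists were made with Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and figures with matplotlib 3.10.9.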

Results

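Mature miRNAs were counted in HFE-145 cells, a human gastric epithelial line, carrying a vector or overexpressing YAP5SA, an active mutant of the Hippo pathway effector YAP, with 2 samples per group. Total counts were 217235 and 195283 in vector replicates 1 and 2, and 136903 and 191954 in YAP5SA replicates 1 and 2. Reads were found for 1802, 1761, 1988 and 1891 miRNAs in the same order. The 4 libraries were dominated by miR-372, a miRNA best known from embryonic stem cells, which took 28.5% of counts in vector replicate 1 (exact binomial 95% interval 28.4 to 28.7), 29.3% in vector replicate 2 (29.1 to 29.5), 28.97% in YAP5SA replicate 1 (28.7 to 29.2) and 35.3% in YAP5SA replicate 2 (35.1 to 35.5). YAP1 mRNA was not analysed here, so the overexpression itself was not checked. Replicates differed beyond sampling noise, with a chi-square per degree of freedom of 28.6 between the vector libraries and 15.1 between the YAP5SA libraries. On log2 CPM the order was the reverse. The vector libraries had a Pearson r of 0.96 and a Spearman rho of 0.91, and the YAP5SA libraries had 0.90 and 0.70.

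The comparison of YAP5SA with vector asked which miRNAs differ in gastric epithelial cells overexpressing YAP5SA. Several abundant miRNAs were lower. miR-21-5p fell 3.61-fold, from 129203 ± 1274 to 35757 ± 6266 CPM (SD, n = 2). In the miR-200 family, known as guardians of the epithelial state, 4 members were called lower, with log2 fold changes of -1.31 to -2.02. Also lower were miR-7-5p, the skin and epithelial miRNA miR-203a, and miR-10a-5p, which lies in the HOXB cluster. The miRNAs that rose were mostly rare in vector cells, such as miR-3132, miR-1243 and miR-1290. Of 602 miRNAs tested, 71 were higher and 21 lower by edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, and 200 had an unadjusted p under 0.05. Among the 66 miRNAs with a mean of at least 1000 CPM, 13 were called lower and 0 higher by edgeR, and 55 had a log2 fold change under 0. This tally rested on the scaling and the libraries: it was 9 lower, 6 higher and 37 under 0 with library totals, 4, 10 and 29 with scaling from abundant miRNAs, and 4, 0 and 60 with scaling from rarely counted miRNAs. Leaving out vector replicate 1 or 2 gave 0 lower and 0 higher, and leaving out YAP5SA replicate 1 or 2 gave 28 and 55 lower with 4 and 0 higher.

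**Figure D1:**
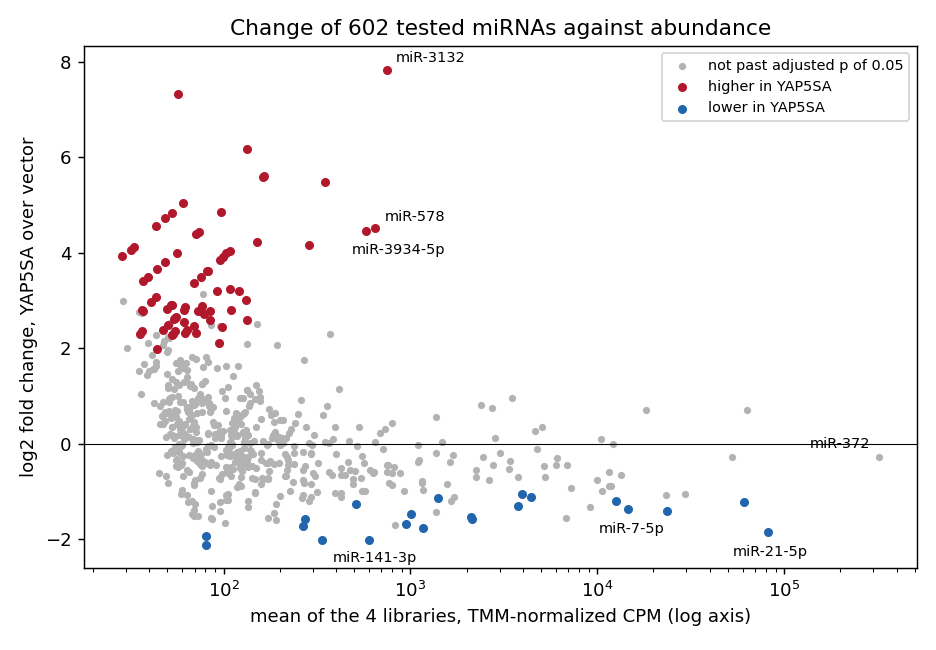
Log2 fold change (YAP5SA over vector, vertical axis) of the 602 tested miRNAs against their mean TMM-normalized CPM over the 4 libraries (log axis); red points are the 71 higher and blue points the 21 lower miRNAs past an adjusted p of 0.05. Fitted fold changes of miRNAs with few vector counts depend on the prior count.

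The miRNA with the largest fall among those named was miR-32-5p, which lies in an intron of TMEM245 on GRCh38 chromosome 9 from 109046229 to 109046298, with a log2 fold change of -2.11 ± 0.50 (SE; adjusted p = 0.033, edgeR). The log2 fold change was -2.03 for miR-135b-5p, from an intron of LEMD1, -1.94 for let-7b-3p, -1.77 for miR-3934-3p, -1.73 for miR-10a-3p and -1.68 for miR-16-2-3p. miR-128, a miRNA best known from neurons, fell by 1.58 on the log2 scale, and miR-615-3p, from an intron of HOXC4 and HOXC5, fell by 1.53. For miR-21-5p the log2 fold change was -1.85 ± 0.28 (SE; adjusted p = 0.023, edgeR); its gene overlaps an exon of VMP1 on GRCh38 chromosome 17 from 59841266 to 59841337. Of the 21 lower miRNAs, 19 had a mean of at least 100 CPM.

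The miR-200 family has the EMT regulators ZEB1 and ZEB2 as known targets, and all 8 tested members had a log2 fold change under 0. Over all miRNAs tested 4 members were called lower, and 7 were lower when adjusted over the list alone. miR-141-3p fell from 959 ± 250 to 235 ± 148 CPM (SD, n = 2), with a log2 fold change of -2.02 ± 0.50 (SE; adjusted p = 0.038, edgeR). It lies on GRCh38 chromosome 12 from 6964097 to 6964191, in an intron of MIR200CHG. The log2 fold change was -1.57 for miR-429, -1.47 for miR-200a-5p and -1.31 for miR-200b-3p, whose genes lie together on GRCh38 chromosome 1 between 1167104 and 1169087. miR-200c-3p had a log2 fold change of -0.76 (adjusted p = 0.099, edgeR) and miR-200a-3p of -1.43 (adjusted p = 0.062, edgeR), and neither passed. The family's median log2 fold change was -1.45, against 0.11 for all tested miRNAs and -0.41 for random lists matched on mean expression. Its difference from the median of all miRNAs was -1.57 with TMM, which other scalings cannot test since they shift all fold changes nearly alike, and -0.96 on the authors' normalized values. Camera with a preset correlation placed the family lower (adjusted p = 0.00062, Benjamini-Hochberg), and the call was lost with adjusted p = 0.65 with an estimated correlation. With all samples, edgeR called 1 member with library totals or with scaling from abundant miRNAs. It called 0 members with the looser filter at 10 CPM, which tested 1791 miRNAs, or the stricter one at 100 CPM, which tested 315. Without vector replicate 1 or 2 edgeR called 0 members, and without YAP5SA replicate 1 or 2 it called 5 and 7.

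**Figure D2:**
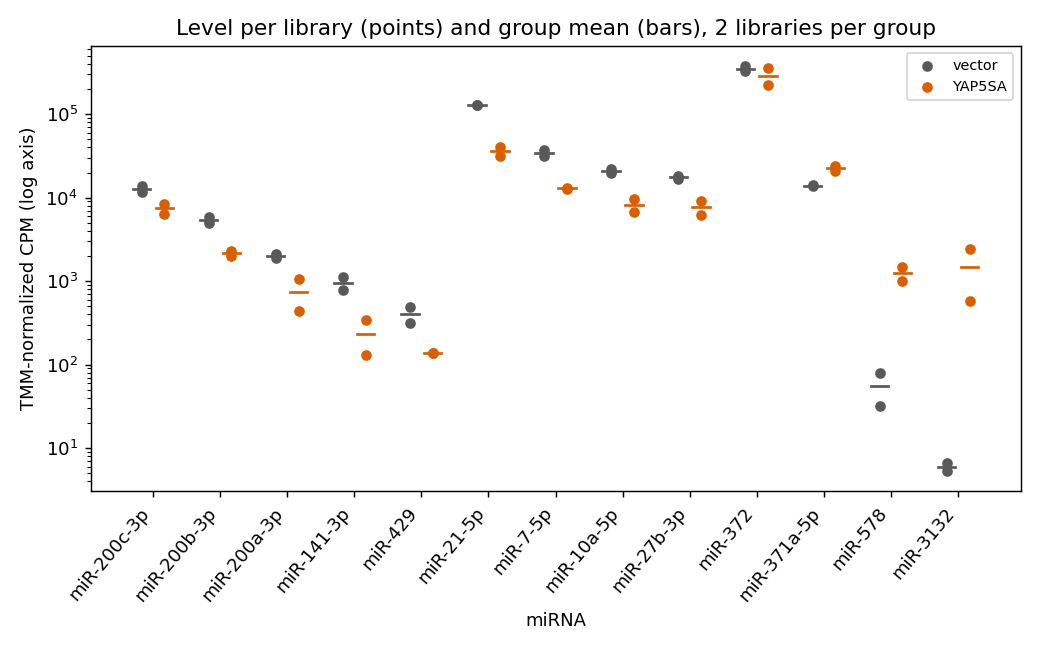
TMM-normalized CPM (log axis) of 13 miRNAs in the 2 vector (grey) and 2 YAP5SA (orange) libraries; points are libraries and bars group means. The YAP5SA points of miR-21-5p lie below its vector points, and those of miR-372 overlap its vector points.

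In the group of miR-10, miR-99, miR-100 and miR-125, 10 of 11 tested members had a log2 fold change under 0. Over all miRNAs tested 4 members were called lower, and 8 were lower when adjusted over the list alone. miR-10a-5p went from 21088 ± 1774 to 8122 ± 2007 CPM (SD, n = 2), and the log2 fold change was -1.38 for it, -1.27 for miR-125b-1-3p and -1.13 for miR-99b-3p. miR-100-5p had a log2 fold change of -1.06 and missed the threshold (adjusted p = 0.0504, edgeR). The group's median was -1.06, with adjusted p = 0.0017 by camera with the preset correlation and adjusted p = 0.65 with an estimated correlation. It was -0.58 with library totals and -0.34 with scaling from abundant miRNAs, with 1 member called in each. The looser filter at 10 CPM and the stricter one at 100 CPM each gave 0 members called. Without YAP5SA replicate 2 the median was -1.83 with 9 members called, without YAP5SA replicate 1 it was -0.86 with 6, and without vector replicate 1 or 2 no member was called. On the authors' values camera did not call the group (adjusted p = 0.18), and its difference from the median of all miRNAs was -0.42 against -1.18. All 8 tested members of the miR-23/27/24 clusters had a log2 fold change under 0. Over all miRNAs tested only miR-27b-3p passed (log2 fold change -1.20 ± 0.29 SE, adjusted p = 0.034, edgeR). The log2 fold change was lower still for miR-27a-5p (-1.56, adjusted p = 0.075, edgeR) and miR-27a-3p (-1.32, adjusted p = 0.054, edgeR). Adjusted over the list alone 4 were lower. The median of the 8 was -1.01, with adjusted p = 0.0038 by camera and adjusted p = 0.72 with an estimated correlation. It was -0.56 with library totals and -0.32 with scaling from abundant miRNAs. Without YAP5SA replicate 2 all 8 were called and the median was -2.08, without YAP5SA replicate 1 it was -0.73 with 3 called, without vector replicate 1 or 2 none was called, and camera did not call the list on the authors' values (adjusted p = 0.13). None of the 9 tested members of the let-7 family, which holds growth-restraining miRNAs, passed edgeR's test over all miRNAs or adjusted over the list alone. The let-7 median was -0.59, with adjusted p = 0.039 by camera and adjusted p = 0.79 with an estimated correlation, and let-7i-5p came closest at -0.93 (adjusted p = 0.052, edgeR). The let-7 median was -0.11 with library totals and 0.14 with scaling from abundant miRNAs, where 8 of 9 members lay above 0. Its difference from the median of all miRNAs was -0.71 in the main fit and -0.70 with scaling from abundant miRNAs. Against random lists matched on mean expression the difference was only -0.06 in the main fit. Without YAP5SA replicate 2 edgeR called 9 of 9 let-7 members lower with a median of -1.32, without YAP5SA replicate 1 it called 2 with -0.47, and without vector replicate 1 or 2 it called 0, with -0.75 and -1.08. The let-7 camera call was also lost with upper quartile scaling (adjusted p = 0.060), library totals (0.149), the replicate block (0.069), without YAP5SA replicate 1 (0.121), with the 100 CPM filter (0.33), with scaling from abundant (0.19) or rarely counted miRNAs (0.080), and on the authors' values (0.81). None of the 19 lists tested passed with an estimated correlation or with fry, and 4 passed with the preset correlation.

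**Figure D3:**
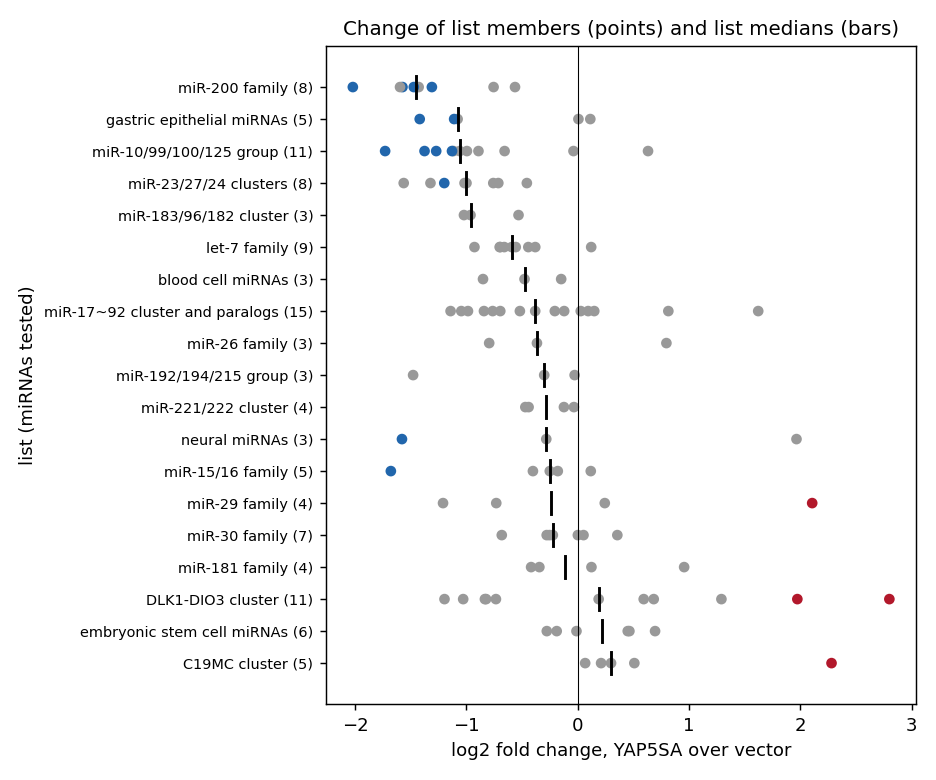
Log2 fold change (YAP5SA over vector, horizontal axis) of the tested members of each of 19 lists (points) with the list median (bars); blue and red points are lower and higher miRNAs past an adjusted p of 0.05, and grey points did not pass. The miR-200 family had the lowest median, -1.45, and 3 list medians lay above 0.

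Among the higher miRNAs, miR-578, from an intron of CPE on GRCh38 chromosome 4 from 165386242 to 165386337, rose from 55.3 ± 33.4 to 1244 ± 338 CPM (SD, n = 2), with a log2 fold change of 4.51 ± 0.52 (SE; adjusted p = 0.012, edgeR). miR-3934-5p, named after its values were seen because it had the smallest p, had counts of 10 and 7 in the vector and 205 and 201 in the YAP5SA libraries (log2 fold change 4.46 ± 0.39 SE, adjusted p = 0.0036, edgeR). miR-3132 had 2 counts over the vector and 562 over the YAP5SA libraries, a ratio of 261 (exact binomial 95% interval 72.0 to 2163). The ratio was 87.4 (15.3 to 3489) for miR-1243, 53.5 (14.5 to 447) for miR-198, whose sequence lies in an exon of FSTL1, and 53.01 (14.3 to 443) for miR-600. These intervals leave out the spread between replicates: YAP5SA replicates 1 and 2 had 585 and 2402 CPM of miR-3132, 432 and 94.2 of miR-1243, 534 and 110 of miR-198, and 488 and 147 of miR-600. The ratio was 40.0 (6.80 to 1616) for miR-5585-5p, 34.4 (5.80 to 1395) for miR-548c-3p and 28.8 (4.804 to 1175) for miR-1290. For miR-4795-3p it was 32.5 (8.68 to 274), and for miR-4742-5p it was 32.5 (5.47 to 1322). In that order, YAP5SA replicates 1 and 2 had 153 and 83.7, 153 and 52.3, 85.2 and 83.7, 114 and 262, and 79.5 and 110 CPM. miR-620 had 0 counts in the vector libraries and 41 in the YAP5SA libraries, with 29 and 12 by replicate. The ratio was 12.7 if the vector group is given a floor of 3 counts, and the lower exact binomial limit was 9.88. miR-4516 passed (adjusted p = 0.048, edgeR) with counts of 2 and 3 against 9 and 252, so YAP5SA replicate 2 carried its rise. Of the 71 higher miRNAs, 64 had at most 5 counts in each vector library. miRNAs under a mean count of 20 took 3.41% and 3.15% of counts in the vector libraries and 10.5% and 5.56% in YAP5SA replicates 1 and 2, so the libraries also differed in how much of the total lay in rare miRNAs.

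The most abundant miRNA, miR-372, had a log2 fold change of -0.28 ± 0.33 (SE; adjusted p = 0.62, edgeR). Of 6 tested embryonic stem cell miRNAs, 0 passed edgeR's test over all miRNAs or adjusted over the list alone, with a median log2 fold change of 0.22. Their camera adjusted p was 0.92, with adjusted p = 0.94 with an estimated correlation. Among the 8 most abundant miRNAs, miR-7-5p fell by 1.42 and miR-3529-3p by 1.22 on the log2 scale. miR-3529-3p lies opposite MIR7-2, 1 of the 3 genes that give miR-7-5p, and their counts cannot be assigned to either strand from this table. The log2 fold change was 0.70 for miR-371b-3p (adjusted p = 0.11, edgeR), -0.28 for miR-4651 (adjusted p = 0.84, edgeR) and -1.08 for miR-148a-3p (adjusted p = 0.064, edgeR), and none of these passed. miR-4651 had 3036 and 15031 counts in the vector replicates, a wide spread within the group.

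Of 5 tested gastric epithelial miRNAs, miR-7-5p and miR-203a were called lower over all miRNAs. Adjusted over the list alone 3 were lower (camera adjusted p = 0.12, or 0.65 with an estimated correlation). No member of the miR-17~92 cluster and paralogs passed edgeR's test, of 15 tested, also when adjusted over the list alone, with a median of -0.38 (camera adjusted p = 0.13). In the cluster of miR-183, miR-96 and miR-182 0 of 3 members passed edgeR's test and 1 was lower when adjusted over the list alone, with a median of -0.96 (camera adjusted p = 0.12). In the miR-15/16 family miR-16-2-3p was the member called lower among 5 tested, and it also passed adjusted over the list alone (camera adjusted p = 0.29). In the miR-29 family miR-29b-2-5p rose by a log2 fold change of 2.11 among 4 tested, and adjusted over the list alone 1 was higher and 1 lower; its median was -0.24 and its mean 0.10 (camera adjusted p = 0.88). From the DLK1-DIO3 cluster, an imprinted locus, miR-134 rose and miR-370 rose among 11 tested, also adjusted over the list alone, the former with a log2 fold change of 1.97 and the latter with a ratio of 7.44 (2.26 to 38.6; camera adjusted p = 0.92). In the C19MC cluster, known from placenta, miR-516b-5p rose by a log2 fold change of 2.28 among 5 tested, also adjusted over the list alone (camera adjusted p = 0.74). No member passed edgeR's test, also when adjusted over the list alone, in the miR-30 (7 tested, camera adjusted p = 0.45), miR-26 (3 tested, 0.74) and miR-181 (4 tested, 0.90) families, the cluster of miR-221 and miR-222 (4 tested, 0.42) or the group of miR-192, miR-194 and miR-215 (3 tested, 0.40). The miR-181 family had a median of -0.11 and a mean of 0.08.

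Among markers of other cell types, miR-128 was the neural member called lower over all miRNAs, of 3 tested. Adjusted over the list alone 1 was higher and 1 lower. The list had a median of -0.28 and a mean of 0.03 (camera adjusted p = 0.74). Blood cell miRNAs had 0 calls by edgeR among 3 tested and 1 lower when adjusted over the list alone (camera adjusted p = 0.29). The family of miR-130 and miR-301 had 2 tested members, and the cluster of miR-143 and miR-145, muscle and endothelial lists had 1 each, none past edgeR's threshold over all miRNAs or adjusted over the list alone. No member of the family of miR-34 and miR-449 or the liver list had enough counts to test. The summed muscle miRNAs were at 211 and 217 CPM in the vector and 568 and 152 CPM in YAP5SA replicates 1 and 2.

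The split of 71 higher to 21 lower became 147 to 12 with library totals alone, where the median log2 fold change of all miRNAs was 0.61 in place of 0.11, 169 to 5 with scaling from abundant miRNAs (median 0.84), and 26 to 16 with scaling from rarely counted miRNAs (median -0.50). Fits with a library left out tested 1042 and 1037 miRNAs without vector replicate 1 and 2, in place of 602. Without YAP5SA replicate 1 and 2 they tested 679 and 949. Such fits thus mix the lost library with another filter and scaling. With all libraries, the filter at a mean of 10 CPM tested 1791 miRNAs, so it was looser than the main filter. Without vector replicate 1 edgeR called 1 higher and 0 lower (112 with unadjusted p under 0.05), without vector replicate 2 it called 13 and 0 (119), without YAP5SA replicate 1 it called 61 and 57, without YAP5SA replicate 2 it called 124 and 159, a filter at a mean of 10 CPM left 19 and 1, and DESeq2 called 17 and 24. A p under 0.05 was given for 190 of 2039 miRNAs in the authors' deposited table, and 0 remained after Benjamini-Hochberg adjustment of those p-values. The authors' deposited table gave miR-21-5p a fold change of 0.479 with p = 0.0089. Of the miRNAs called by edgeR, 44 had p under 0.05 in the same direction in the authors' deposited table.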

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

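The scalings from abundant or from rarely counted miRNAs, the 100 CPM filter and limma on the authors' log2 values were chosen after seeing the data. Of 862 values of single named miRNAs under the alternatives, 842 kept their direction, 574 of these also their side of the threshold, 46 gaining it and 25.8% of all values losing it, and 20 changed direction, 0 of these among miRNAs past the threshold. All 21 lower miRNAs stayed under 0 wherever tested. The miR-200 family passed camera with the preset correlation under each alternative run with it, but not camera with an estimated correlation (adjusted p = 0.65).

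Calls moved from 71 higher and 21 lower to 147 and 12 with library totals alone, 169 and 5 with scaling from abundant miRNAs, and 26 higher with scaling from rarely counted miRNAs, where the factors shift all fold changes. Higher calls numbered 34 without a filter, where 8 lists passed. The 10 CPM filter tested 1791 miRNAs, more than the main fit, and gave 19 higher and 1 lower. The 100 CPM filter tested 315 and gave 25 and 1. DESeq2 called 17 higher, limma-voom 21 higher and 10 lower, and limma on the authors' log2 values 9 and 1, with 1 list. DESeq2 gave no adjusted p for 1503 of 2039 miRNAs, among them miR-620 and miR-1290, so it could not call these. Camera with an estimated correlation and fry passed 0 lists, against 4. Otherwise the cause of the changes with filter and tool was not tested.

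The labels do not say whether replicates of the same number were paired. The correlation of replicate differences between groups was 0.016 over the tested miRNAs, many of them rare, which does not settle it. The replicate block gave 102 higher and 34 lower, including all 71 and 21. Fits with a library left out also changed the filter and the scaling, and each tested more miRNAs than the main fit. Leaving out 1 library gave 1 to 124 higher, 0 to 159 lower and 3 to 6 lists; the lone sample left is then assumed to vary like the other group.

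Values that changed direction belonged to miRNAs that had not passed. miR-372 was 0.20 with library totals, 0.13 with the 100 CPM filter, 0.44 with abundant scaling and 0 on the authors' values, where the highest value, that of miR-372, was equal in each library. miR-4651 was 0.22, 0.14, 0.38 and 0.73 in the same order, 0.14 with the replicate block, 0.17 with limma-voom and from -1.49 to 1.25 with each library left out in turn. let-7a-5p was 0.025 with library totals, 0.28 with abundant scaling and 0.14 on the authors' values. let-7f-5p was 0.14 with abundant scaling and 0.14 on the authors' values. With abundant scaling let-7g-5p was 0.067 and miR-125a-5p 0.077, and miR-200c-3p was 0.066 on the authors' values. Under scalings the cause is the shift in factors. For miR-372 on the authors' values, the 0 follows from the equal highest value. Elsewhere the cause was not tested.

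Precursor alternatives gave no value because each mature name occurs once, and those for normalized values were not run because counts were present. Depth limited rare miRNAs, since 1 count equals 5.23 to 6.57 CPM.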

Other observations

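The scaling from rarely counted miRNAs, both tests of a uniform rise with it, the test of opposite-strand counts and the alternatives added later were chosen after the result was seen; the other tests were not.

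Across 84 hairpins with both arms tested, the log2 fold changes of the 5p and 3p arms had a Spearman rho of 0.50 and a Pearson r of 0.40, across hairpins, which are not independent replicates. miR-3934 had its 5p arm at 4.46 and its 3p arm at -1.77, both past the threshold. Arms differed in sign in 6 of the 21 hairpins with a called arm, and of 3 with both arms called 1 was opposite. Such opposite calls were found in 4.76% of the 21, an exact 95% interval of 0.12 to 23.8, too wide to say whether arms of a hairpin change independently in these libraries. The miR-3934 gene lies on GRCh38 chromosome 6 from 33698128 to 33698234, opposite an exon of UQCC2.

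Most miRNAs higher in YAP5SA had few counts in the vector libraries. Of the 71, 0 shared a run of 16 bases with any of 11 annotated YAP1 transcripts, as did 0 of the 531 other tested miRNAs. This argues against YAP fragments with such an exact run. The YAP5SA construct and shorter or mismatched runs were not searched. Of the higher miRNAs, 11 (15.5%) lay whole in another annotated transcript, such as miR-1246 in RNU2-1, against 21.9% of the other tested miRNAs. The ratio was 0.71 (interval 0.40 to 1.25, two-sided Fisher's exact p = 0.28). This argues against such fragments as a general source, but not for the 11. Introns were not searched, and several higher miRNAs named above lie in introns on the same strand. Scaling factors from rarely counted miRNAs took the median log2 fold change of those tested from 0.66 to 0.03. Of the 71, 26 stayed past the threshold, with a median going from 4.44 (median SE 0.80) to 3.84 (0.77). By a first criterion this share of 36.6% (interval 25.5 to 48.9) could not tell whether background reads rose by 1 factor. A second criterion counted the 26 against such a rise as their whole cause, but its bound was set after the 26 was known. The 26 were also picked for being called before and after the scaling, so the test does not settle the question for them. With vector replicate 1 or 2 left out these had medians of 3.76 and 3.45 but none was called, as the SE rose to 1.15 and 1.08, and with YAP5SA replicate 1 or 2 left out 21 and 25 were called. The other 45 went from 2.78 (0.64) to 2.18 (0.75), lower folds with a wider spread that ended the calls. For them too a uniform rise cannot be told apart from a change caused by YAP5SA, an untested hypothesis.

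Several abundant miRNA lists were lower in YAP5SA, which could come from a shift of all abundant miRNAs. The embryonic stem cell list had a median of 0.22, at percentile 98.2 of the random lists below, but its members went both ways. Its 262265 to 405588 summed CPM were mostly miR-372 (log2 fold change -0.28). Its median lay between miR-371a-3p (-0.01) and the rarer miR-302b-3p (0.45, mean 185 CPM). Without vector replicate 1 or 2 the median was 0.10 and -0.29, and without YAP5SA replicate 1 or 2 it was 0.31 and -0.68. This list thus does not settle the question. Against 10000 random lists matched on mean expression, the miR-200 median lay at percentile 0.01, the smallest they can give, and the miR-23/27/24 median at 0.26. The median of the miR-10, miR-99, miR-100 and miR-125 group lay at 2.05 (Monte Carlo interval 1.77 to 2.34), close to the bound of 2.5. Random lists drew members independently, whereas the estimated correlation within these lists was 0.34, 0.72 and 0.26 in that order. The percentiles may thus be too extreme, and they do not settle whether a shift of all abundant miRNAs was the whole cause. The let-7 median lay at percentile 45.4 and that of miR-30 at 67.3, both in line with a shift of all abundant miRNAs. The miR-200 median lay 1.57 below that of all miRNAs with TMM, a wider gap than against the matched lists. It is a hypothesis that YAP5SA lowers this family, since other causes stay open. No list passed with an estimated correlation, but that test cannot decide for or against a list here.

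Of 14 pairs of miRNAs with complementary sequences, 9 had counts within a factor of 1.5, such as miR-203a over miR-203b-5p (ratio 1.11). The ratio was 2.56 for miR-3529-3p over miR-7-5p, 0.288 for miR-371a-5p over miR-371b-3p, 6.14 for miR-103b over miR-107, 8.21 for miR-371a-3p over miR-371b-5p and 21.5 for miR-24-3p over miR-3074-5p. The median absolute log2 ratio was 0.243, a 1.18-fold difference, and 0 of 10000 shuffles of the partners gave as low a value, with a median ratio of 3.18 on the log2 scale. The similarity was seen before this test was chosen, so whether reads of either strand were counted for both entries cannot be told apart from similar levels of both. Such entries held 18.99% to 24.1% of counts per library, and no biological explanation was tested.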
